A study of Mus musculus with 12 samples.

How the data were processed

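Total RNA of BV-2 cells was labelled with Cy3 and hybridised to one-colour arrays, per the labels' protocols. The spots were extracted with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. The background correction, the normalization and the probe annotation are not given in the sources used here. The deposited table holds 1 value per probe and array for 166924 probes and 12 arrays. The deposited values were read as log2 intensities because their range, 1.17 to 18.84, would exceed a scanner's range as natural or decimal logs; the base itself is not stated. The quartiles of the 12 arrays differed by at most 0.000336, as after quantile normalization, so the values were used as deposited. A normalization of this kind removes any difference in total signal between groups. The table has no flags or detection calls, so probes near background could not be marked, and a fold against a dim group has no formal bound. The number of arrays limits the precision.

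Groups and replicate numbers came from the sample titles. The series' design text gives 3 repeats of the experiment, and does not say how cultures were handled in each; p-values measure the spread between these arrays. No sample's values were left out of the main comparisons, and 0 value columns belonged to other samples.

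Probes above the array median in at least 3 of 12 arrays were kept, 91034 in all. A model with a mean for each of the 4 groups was fitted to all 12 arrays with lmFit and eBayes (limma 3.58.1, R 4.3.3, 8 residual degrees of freedom). The contrasts were LPS against vehicle at each temperature, 33 °C against 37 °C with and without LPS, and the interaction. A probe was called at a Benjamini-Hochberg adjusted p below 0.05, two-sided, with no fold minimum. Sets of LPS-induced and LPS-repressed probes were taken from the LPS effect averaged over both temperatures (adjusted p below 0.05 and at least 2-fold) and tested on the interaction with fry, adjusted over both sets. Plots were drawn with matplotlib 3.10.9.

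The design, the filter, the threshold, most alternatives and the rule for naming were fixed before the data were examined. That rule took, per contrast, the 10 largest rises and the 10 largest falls among called features whose groups did not overlap (no such condition for the interaction). It also named Cirbp, Rbm3, Tnf, Il1b, Il6, Nos2 and Ptgs2 whatever their result. No table used here pairs these probe identifiers with genes, and the gene tables at hand matched none, so features were probes. At most 2 probes that rose and 2 that fell are printed per contrast, and those genes were not analysed here. For the same reason 26 gene lists holding 391 genes, covering inflammation, interferon, cold and heat responses, metabolism and cell type markers, were not tested. The averaging of several probes per gene did not apply.

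Several results were added after the values had been seen. These are the comparison of the temperature shifts with and without LPS, the counts shared between contrasts in one direction, the set of LPS-repressed probes tested separately, the tests of probe classes, and the scores of the temperature probes per array. The classes came from the start of the probe identifiers and were compared with the remaining probes with camera, at a preset correlation of 0.01 and at an estimated one.

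Alternatives tried were another quantile normalization, scaling to the 75th percentile, no filter, a filter at the 75th percentile, a trended and robust variance, array weights, a fit of only the groups compared, the replicate number as a block, a 2-fold minimum, and leaving out each array. After seeing the data 3 more were added: a term for the vehicle 37 °C arrays together with LPS 37 °C replicate 1, LPS 37 °C replicate 1 as the only array of its group, and blocks of 4 consecutive arrays in deposition order. Neither the term nor the blocks are recorded by the labels, which name no slides or dates.

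The fits were tested on simulated data with 91034 probes, of which 50 changed by 0.5, 100 by 1 and 50 by 2 on the log2 scale. For LPS at 37 °C, 4%, 56% and 88% of these were recovered, with 3 false calls. For the interaction the shares were 0%, 31% and 58%, with 3 false calls. The simulated noise was independent between probes and between arrays, without the array structure described below. Fewer probes changed than were called in the data. These shares check the fits and do not measure recovery or false calls in the real contrasts.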

Results

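The study asked how BV-2 cells, an immortalised mouse microglial line, change their RNA during activation when they are held at a mildly hypothermic temperature. Cells received lipopolysaccharide (LPS, a bacterial cell wall component that activates microglia through Toll-like receptor 4) at 1000 ng/ml or vehicle, and were kept at 37 °C or 33 °C for 4 h. Each of the 4 groups had 3 one-colour arrays, 12 in all. The values cover 166924 probes, of which 151603 carry cluster identifiers (starting mclstr), 4297 carry mmu_circ identifiers and 11024 carry MMU_CIRCpedia identifiers, the last pair being named for circular RNAs. All 12 arrays shared a median of 4.23 and an upper quartile of 6.93 on the log2 scale, as the normalization sets them, so the values do not show whether arrays differed in total signal. The files used here do not pair probes with genes, so results are given per probe and no gene is named. After the filter on dim probes, 91034 probes were tested.

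LPS at 37 °C changed 17366 probes, of which 9184 rose and 8182 fell. The response was uneven in size: 3007 probes rose and 1268 fell at least 2-fold, and 97 rose against 2 that fell at least 16-fold. Probe mclstr_119012_149_14 went from 2.20 ± 0.42 in vehicle to 13.36 ± 0.19 with LPS (SD, n = 3), and mclstr_37615_1878_10 went from 4.10 ± 0.63 to 15.03 ± 0.10 (SD, n = 3). The largest falls were those of mclstr_42348_1056_6, from 6.48 ± 0.12 to 2.29 ± 0.92, and of mclstr_14166_3642_3, from 9.45 ± 0.15 to 5.32 ± 0.62 (SD, n = 3). In limma these changes were 11.16 (SE 0.38, adjusted p = 2.98e-08), 10.93 (SE 0.26, adjusted p = 2.81e-09), -4.19 (SE 0.60, adjusted p = 0.000821) and -4.13 (SE 0.25, adjusted p = 1.71e-06) on the log2 scale. The values of both groups did not overlap for 36.1% of probes, against 10% by chance.

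The vehicle means of both induced probes, and the LPS mean of mclstr_42348_1056_6, lay below the array median, where a fold change has no firm size. LPS 37 °C replicate 1 stood apart from replicates 2 and 3, with a mean correlation of 0.977 to them against 0.989 between them, and 27228 probes were called without it. The count was 28643 with array weights, 11537 with only the 2 groups fitted and, in settings chosen after seeing the data, 10902 with a term for the arrays that replicate 1 resembles, 10104 with replicate 1 as the only LPS 37 °C array and 9288 with blocks of 4 arrays in deposition order.

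LPS at 33 °C changed 10477 probes, of which 5146 rose and 5331 fell, with 1825 rising and 1019 falling at least 2-fold. Most of the 10 largest rises were also among the 10 largest at 37 °C, while many of the 10 largest falls were not. Probe mclstr_119012_149_14 rose from 3.52 ± 0.91 to 13.48 ± 0.09, and mclstr_80804_449_16, well above the array median throughout, rose from 7.10 ± 0.20 to 16.99 ± 0.10 (SD, n = 3). Probe mclstr_42348_1056_6 fell from 6.47 ± 0.16 to 2.10 ± 1.35, and mclstr_14166_3642_3 from 9.65 ± 0.15 to 5.56 ± 0.12 (SD, n = 3). In limma the changes were 9.95 (SE 0.38, adjusted p = 9.05e-08), 9.89 (SE 0.12, adjusted p = 1.13e-10), -4.37 (SE 0.60, adjusted p = 0.000938) and -4.08 (SE 0.25, adjusted p = 3.13e-06). Non-overlapping groups were found for 31.8% of probes, against 10% by chance, and without LPS 33 °C replicate 3 the count of called probes was 6928. The count was 4939 with the blocks and 32501 with array weights. Those weights were 5.80 for LPS 33 °C replicate 3, 3.82 for vehicle 33 °C replicate 3 and 0.41 to 0.85 for the other 33 °C arrays. The weighted count therefore rests mainly on replicate 3 of each group.

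The LPS responses at both temperatures, which share no arrays, overlapped. Among the induced probes 3775 were called at both temperatures, where independent lists would share 519, and among the repressed probes 2974 were shared, where 479 would be. The 6749 probes shared in one direction became 12258 with array weights and 3446 with the blocks, a count chosen after seeing the data. Opposite calls were rare, with 63 probes that rose at 37 °C falling at 33 °C and 15 that fell at 37 °C rising at 33 °C. Across probes, which are not independent replicates, the log2 changes correlated at 0.51 with a slope of 0.43 for 33 °C on 37 °C. Noise in the 37 °C changes of unresponsive probes lowers such a slope, so it does not measure the relative response. Among probes called at both temperatures the medians at 37 °C and 33 °C were 1.03 and 0.86 for induced probes. For repressed probes they were -0.69 and -0.63. The correlation was 0.24 with no filter on dim probes and 0.74 with a stricter one.

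**Figure D1:**
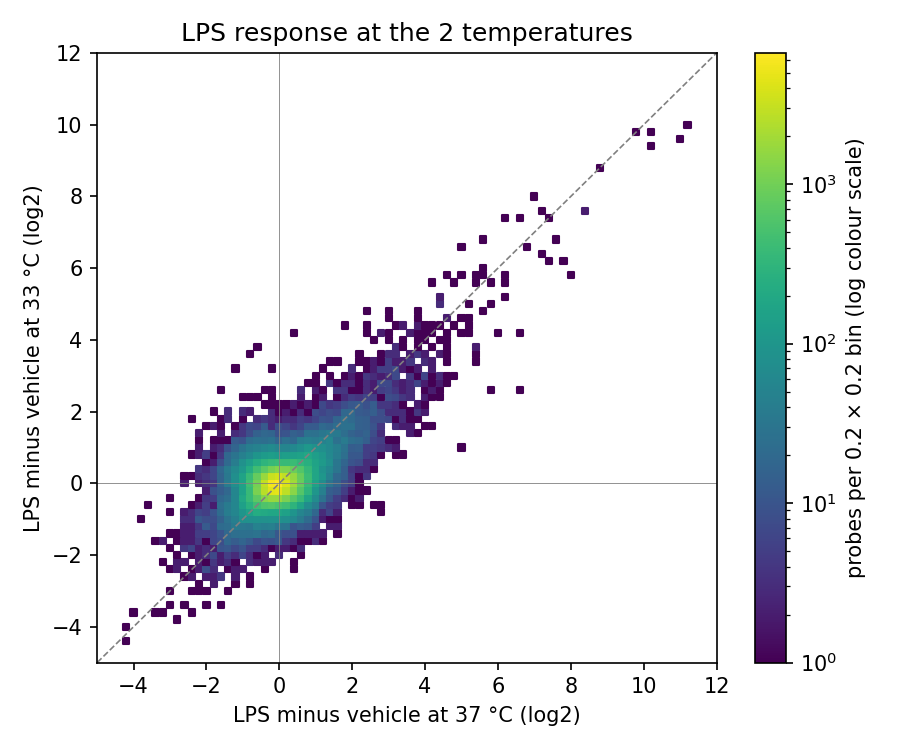
LPS minus vehicle on the log2 scale for the 91034 tested probes at 37 °C (horizontal) and 33 °C (vertical), each square being a bin of 0.2 by 0.2 coloured by its number of probes on a log colour scale, with a dashed line of equal response. Of the 588 probes induced at least 4-fold in the average of both temperatures, 67.7% lie below the dashed line. The cloud of unresponsive probes is centred on 0.

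Without LPS, 13723 probes differed between 33 °C and 37 °C, of which 8107 were higher and 5616 lower at 33 °C. At least 2-fold changes numbered 1693 upward and 1479 downward. Probe mclstr_82810_906_14 went from 1.97 ± 0.46 at 37 °C to 7.04 ± 0.14 at 33 °C, and mclstr_76108_971_12 from 2.60 ± 1.21 to 6.78 ± 0.15 (SD, n = 3). Probe mclstr_69440_1236_18 went from 5.10 ± 0.07 to 1.83 ± 0.22, and mclstr_112656_621_14 from 5.86 ± 0.38 to 2.70 ± 1.46 (SD, n = 3). In limma the changes were 5.07 (SE 0.32, adjusted p = 4.55e-05), 4.17 (SE 0.62, adjusted p = 0.00322), -3.27 (SE 0.63, adjusted p = 0.0107) and -3.16 (SE 0.88, adjusted p = 0.0389), and the lower mean of each lay below the array median. The groups did not overlap for 45.5% of probes, against 10% by chance.

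Leaving out an array lowers the power of the test, so a smaller count alone does not show reliance on that array. The count moved with the arrays used. It was 5104, 5819 and 6032 without vehicle 37 °C replicates 1, 2 and 3, 7810, 6405 and 7687 without vehicle 33 °C replicates 1, 2 and 3, and 22835 without LPS 37 °C replicate 1, which enters only through the shared estimate of spread. It was 6551 with no filter on dim probes, 35163 with array weights and 22186 with replicate 1 as the only LPS 37 °C array. With a model term, chosen after seeing the data, for the 3 vehicle 37 °C arrays together with LPS 37 °C replicate 1, the count was 558; that term rests on replicate 1 against replicates 2 and 3 alone, so lost calls do not show absent effects. With a term for consecutive blocks of 4 arrays in deposition order, also chosen after seeing the data, it was 172. Of the 4 named probes only mclstr_82810_906_14 kept its call in limma under both. With the first term mclstr_76108_971_12 was at 2.22 (SE 0.89, adjusted p = 0.411), mclstr_69440_1236_18 at -0.81 (SE 0.70, adjusted p = 0.813) and mclstr_112656_621_14 at -0.69 (SE 1.35, adjusted p = 0.946). Over all settings that could move them, adjusted p ranged from 0.00017 to 0.553, from 9.1e-05 to 0.872 and from 0.0156 to 0.946, and mclstr_112656_621_14 lost its call in 10 of 20.

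**Figure D2:**
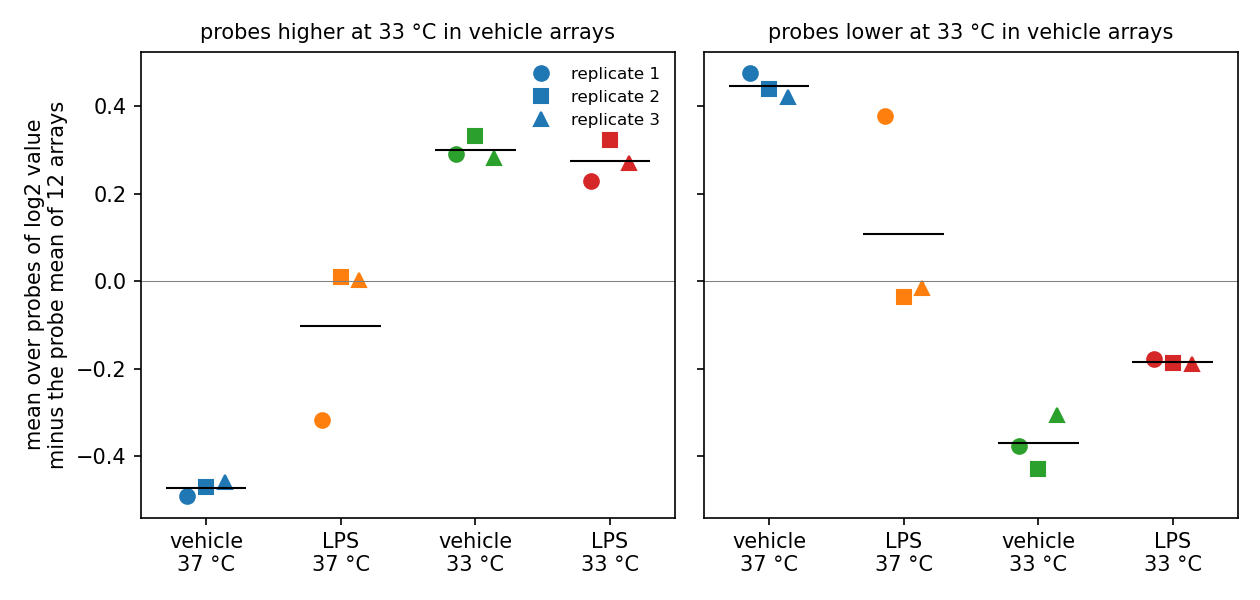
Mean log2 value of the 8107 probes higher (left) and the 5616 lower (right) at 33 °C in vehicle arrays, each probe taken relative to its mean over all 12 arrays, with points for arrays and black lines for group means. The vehicle arrays chose these probes; among the LPS 37 °C arrays replicate 1 lay at -0.32 on the left and 0.38 on the right, while replicates 2 and 3 lay at 0.01 and 0.00 on the left and at -0.04 and -0.02 on the right.

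With LPS, 11674 probes differed between 33 °C and 37 °C, of which 6868 were higher and 4806 lower at 33 °C. At least 2-fold changes numbered 1107 upward and 751 downward. Probe mclstr_82810_906_14, the leading probe of the vehicle comparison, again led, from 2.27 ± 0.67 to 6.72 ± 0.23, followed by mclstr_59039_1373_10, from 1.68 ± 0.84 to 5.60 ± 0.21 (SD, n = 3). Downward, mclstr_141951_183_4 went from 6.28 ± 0.52 to 2.96 ± 1.04, and mclstr_54568_1032_10 from 4.57 ± 0.13 to 1.35 ± 0.17 (SD, n = 3). In limma these changes were 4.45 (SE 0.32, adjusted p = 4.43e-05), 3.93 (SE 0.50, adjusted p = 0.00105), -3.32 (SE 0.53, adjusted p = 0.00328) and -3.21 (SE 0.44, adjusted p = 0.00141), each with its lower mean below the array median. The groups did not overlap for 30.1% of probes, against 10% by chance.

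Without LPS 37 °C replicate 1, 5870 probes were higher and 5934 lower at 33 °C, so the excess of higher probes was not there, and 9012 of the 11674 probes were called again in the same direction. The counts were 7355 without LPS 37 °C replicate 3, 7648 without LPS 33 °C replicate 2 and 6847 without LPS 33 °C replicate 3, and 3006 with only the 2 groups fitted, 7207 with no filter on dim probes and 19519 with array weights. With the term for blocks of 4 arrays in deposition order the count was 746. There mclstr_59039_1373_10 had a like fold with a wider error, 3.80 (SE 1.00), and did not pass in limma (adjusted p = 0.142, from 8.04e-05 to 0.142 over its settings). With LPS 37 °C replicate 1 as the only LPS 37 °C array, mclstr_141951_183_4 was at -2.72 (SE 0.78) and did not pass in limma (adjusted p = 0.0521, from 0.000853 to 0.0521 over its settings).

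The temperature lists with and without LPS, which share no arrays, held 2833 probes higher at 33 °C in both, where independent lists would share 612, and 1330 lower in both, where 296 would be shared. Opposite calls numbered 158 and 53. Across probes the 33 °C shifts with and without LPS correlated at 0.35, and this value depended on 1 array: it was 0.65 against LPS 37 °C replicate 1 alone and 0.07 against replicates 2 and 3. The count of 4163 probes shared in one direction was 2318, 2413 and 2468 without vehicle 37 °C replicates 1, 2 and 3, 2620 without vehicle 33 °C replicate 3 and 2674 without LPS 33 °C replicate 3. It was 2205 with no filter on dim probes, 7899 with array weights, 8660 with replicate 1 as the only LPS 37 °C array, 415 with the term for the arrays it resembles and 95 with the blocks.

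The LPS response itself differed between temperatures for 1401 probes, of which 998 had a lower and 403 a higher LPS effect at 33 °C. Of the 998, 813 rose with LPS at 37 °C and 336 at 33 °C, while 464 were higher at 33 °C without LPS and 692 lower at 33 °C with LPS; these counts share arrays with the interaction and only describe it. Probe mclstr_11633_2281_7 rose from 1.38 ± 0.05 to 8.04 ± 0.02 at 37 °C and from 3.18 ± 0.83 to 5.84 ± 0.25 at 33 °C (SD, n = 3). Probe mclstr_70779_138_15 went from 5.32 ± 0.30 to 2.91 ± 0.41 with LPS at 37 °C, and from 3.63 ± 0.75 to 4.52 ± 0.34 at 33 °C (SD, n = 3). Their interaction values in limma were -4.003 (SE 0.46, adjusted p = 0.0048) and 3.30 (SE 0.50, adjusted p = 0.0147). Both rest on means below the array median (both vehicle means of the first; LPS at 37 °C and vehicle at 33 °C of the second), where the size of a log2 difference is not firm.

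Here too, a smaller count with an array left out can come from the lost power alone. The number of called probes moved with nearly any array. It was 516, 566 and 498 without vehicle 37 °C replicates 1, 2 and 3, 12863, 604 and 587 without LPS 37 °C replicates 1, 2 and 3, 617 and 605 without vehicle 33 °C replicates 2 and 3, and 607 and 521 without LPS 33 °C replicates 1 and 3. Without LPS 37 °C replicate 1 the 33 °C shift with LPS correlated at only 0.07 with the shift without LPS. A vehicle shift that the LPS arrays do not share enters the interaction, and part of it may be a batch, as given below. The 12863 calls therefore need not be changed LPS responses. All 1401 probes were among the 12863, of which 7217 had a lower and 5646 a higher LPS effect at 33 °C, a more even split. It was 503 with no filter on dim probes, 3297 with a stricter one, 3247 with a trended, robust variance, 20335 with array weights, 624 with the term for the arrays replicate 1 resembles and 390 with replicate 1 as the only LPS 37 °C array. With the replicate number as a block 809 probes were called, and with the term for blocks of 4 arrays in deposition order 53. There mclstr_11633_2281_7 was at -4.62 (SE 0.57) and mclstr_70779_138_15 at 2.52 (SE 0.69), and neither passed in limma (adjusted p = 0.05003 and 0.299, the highest over their settings, the lowest being 0.000262 and 0.00145).

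The LPS-induced probes as a set rose less at 33 °C. The set held the 2144 probes that rose at least 2-fold in the average of both temperatures. That choice does not favour either temperature while both LPS effects are equally precise, as in the main fit. Settings that make the 37 °C effect less precise choose the set again, which can push its median interaction down. The median LPS effect of the set was 1.74 at 37 °C and 1.37 at 33 °C on the log2 scale. The median interaction was -0.32 (quartiles -0.78 and 0.08), 71.1% of the probes lay below 0, and limma's fry gave adjusted p = 0.00113 over the induced and repressed sets. Per array the median effect was 1.60, 1.84 and 1.81 in LPS 37 °C replicates 1, 2 and 3, and 1.33, 1.47 and 1.40 in LPS 33 °C replicates 1, 2 and 3. With the term for blocks of 4 arrays in deposition order, chosen after seeing the data, the median interaction was -0.17 (adjusted p = 0.0111 in limma's fry, from 2.34e-05 to 0.0111 over the settings). The 588 probes induced at least 4-fold had a median interaction of -0.36. In vehicle arrays the induced set lay higher at 33 °C, with a median of 0.23, and with LPS it lay lower, with a median of -0.10. The 872 LPS-repressed probes had a median interaction of 0.08 (adjusted p = 0.21 in limma's fry). Without LPS 37 °C replicate 1 the set was chosen again, and its median was 0.23 (adjusted p = 0.00513 in limma's fry). The 37 °C effect is then less precise, and the choice itself can push this median up. The repressed median was also larger with the settings added for the array structure, as given below.

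**Figure D3:**
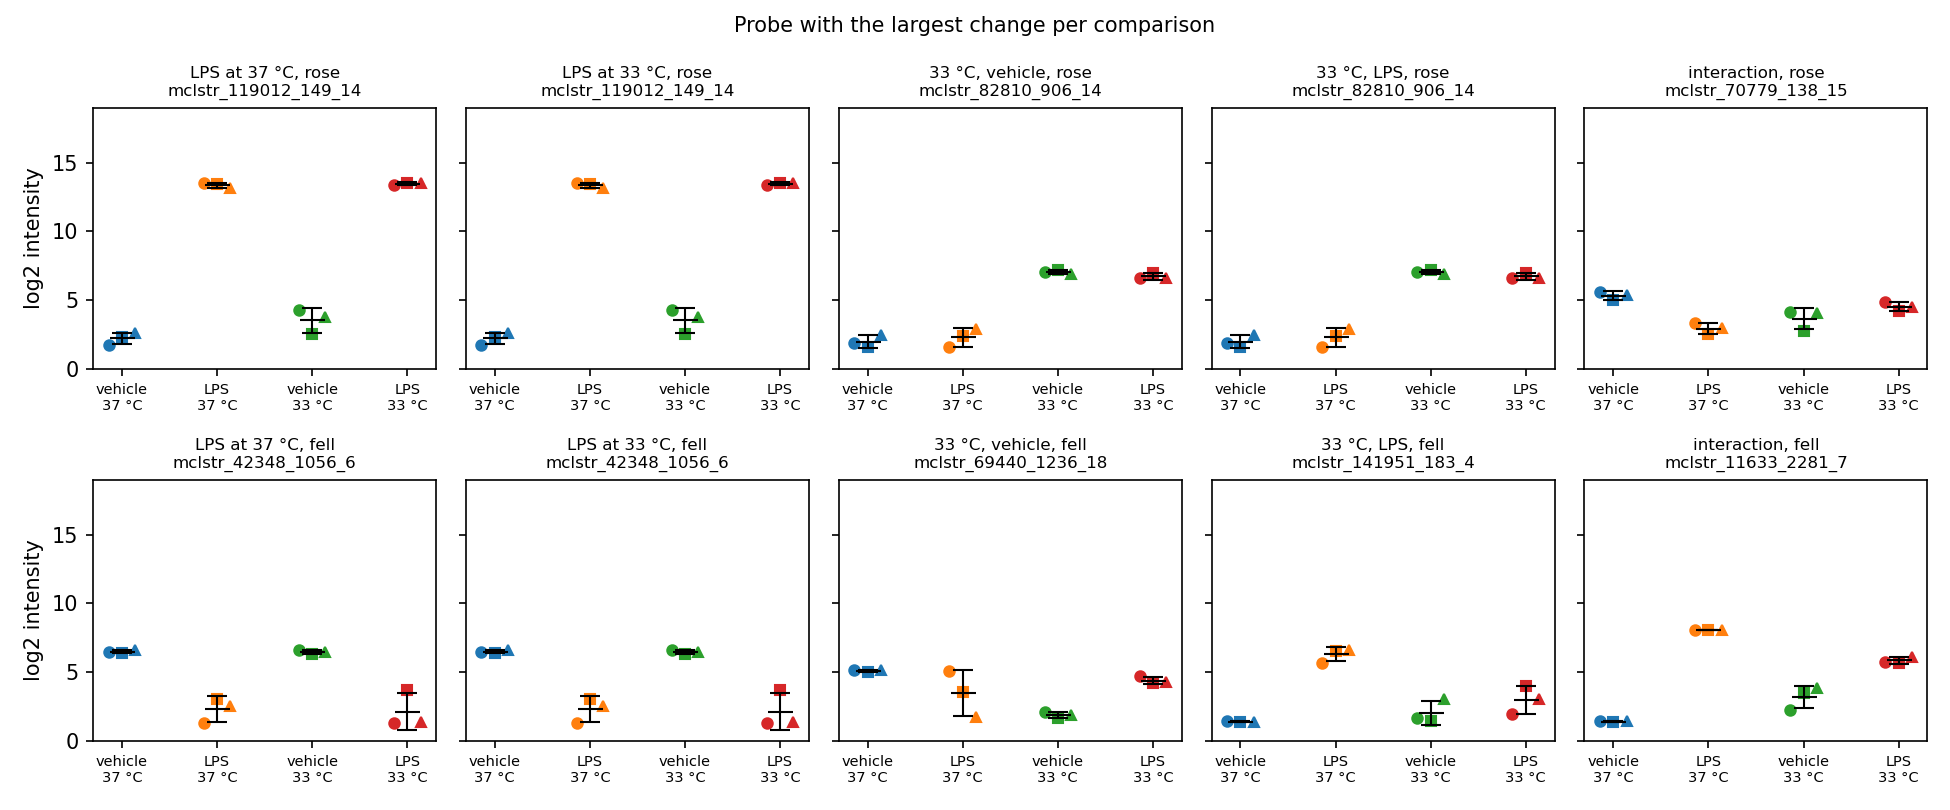
Log2 intensity of the probe with the largest rise (top) and fall (bottom) in each comparison, with points for arrays (circle, square and triangle for replicates 1, 2 and 3) and bars for the mean and SD of the 3 arrays of a group. Probe mclstr_82810_906_14 lay between 6.72 and 7.04 in the group means at 33 °C and between 1.97 and 2.27 at 37 °C, with or without LPS.

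Among probes with circular RNA identifiers, calls at 33 °C with LPS were mostly upward, and whether these classes shifted as a whole depended on the test. Of 8780 MMU_CIRCpedia probes tested, 921 were higher and 245 lower at 33 °C with LPS (10.5% and 2.8%). Of 3281 mmu_circ probes 320 were higher and 108 lower (9.8% and 3.3%), against 7.1% and 5.6% of the cluster probes. Relative to the cluster probes the median shift was 0.14 and 0.11 on the log2 scale, with limma's camera giving adjusted p = 0.000591 and 0.0201 over 10 tests at a preset correlation. With an estimated correlation neither passed (adjusted p = 0.851 for both). Per array, the median of the MMU_CIRCpedia probes minus that of the cluster probes, an offset that can be compared only between arrays, was 1.30 ± 0.08 with LPS at 37 °C and 1.44 ± 0.004 at 33 °C (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). Without LPS the difference between temperatures was 0.01 (exact permutation p = 1), and the vehicle 33 °C arrays alone ranged from 1.28 to 1.49.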

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

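The tests of the array structure and of probe brightness were chosen after the results had been seen; the tests of the LPS-induced set and the splits of the samples were written before their values were computed. The checks of what those 2 tests can exclude, of the residuals of the splits and of the arrays behind the batch term, were added after the values had been seen.

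The LPS response differed between 33 °C and 37 °C, by the interaction test, for 1401 probes. Of 100 splits of temperature within the vehicle and LPS arrays, the real one included, 4 gave as many called probes, but this does not exclude chance: splits that mix temperatures carry the temperature effect in their residuals, and the median residual variance was 0.0736 in the other splits against 0.0426 in the real one. Of the 9 splits drawn that keep the vehicle arrays at their own temperatures, 4 gave as many, the real one included. The highest other split called 20729; it exchanges the temperature labels in the LPS arrays alone and so counts the main effect of temperature. A split that sets LPS 37 °C replicate 2 with LPS 33 °C replicates 2 and 3 gave 5272, and one that exchanges LPS 37 °C replicate 1 with LPS 33 °C replicate 1 gave 2620. These splits leave the vehicle temperature shift in the interaction, so such counts do not measure a structure among the LPS arrays alone. Exchanging LPS 37 °C replicate 2 or 3 with LPS 33 °C replicate 1 gave 0, however. The calls thus depended on where LPS 37 °C replicate 1 was placed, and the splits do not show why. The same test picked out mclstr_70779_138_15 (interaction 3.30), mclstr_50422_1321_6 (3.02), mclstr_11633_2281_7 (-4.003) and mclstr_141951_183_4 (-3.98), in log2. Over the settings that could move them these values ranged from 2.52 to 3.54, 2.66 to 3.51, -4.62 to -3.69 and -4.87 to -3.38, so each kept its direction. Their calls in limma were lost in 3 of 19, 12 of 19, 1 of 20 and 13 of 19 settings that could move them, with adjusted p of up to 0.299, 0.293, 0.05003 and 0.228.

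The 33 °C shift of the vehicle arrays recurred within the LPS 37 °C group: the departure of LPS 37 °C replicate 1 from replicates 2 and 3 correlated at 0.617 across probes with vehicle 37 °C minus vehicle 33 °C, which shares no arrays with it. The correlation was 0.623 among 45069 probes that LPS left within 0.2 at 33 °C. They were not chosen at 37 °C, so this does not exclude weaker stimulation of replicate 1. The LPS-induced set rose less in replicate 1 (median 1.60 against 1.84 and 1.81), but the LPS-repressed set fell further (-1.56 against -1.26 and -1.34). Uniformly weaker stimulation is thus argued against by the repressed set only. An unrecorded batch shared by the vehicle 37 °C arrays and LPS 37 °C replicate 1 may account for the departure of replicate 1. Part of the vehicle temperature contrast would then be that batch. These 4 arrays are also the first 4 in deposition order, and blocks of 4 in that order stay open: vehicle 33 °C replicate 3, which would fall in another block than replicates 1 and 2, lay no further from their mean (SD 0.36) than they from each other (SD 0.45), but its departure correlated at 0.118 with LPS 33 °C minus LPS 37 °C replicates 2 and 3, the direction the blocks need. Whether replicates 2 and 3 were instead 33 °C cultures with wrong labels cannot be told apart: among the 320 vehicle temperature probes of at least 4-fold, LPS 33 °C lay beyond them in the direction of the change by a median of 1.107, but with a lower quartile of -0.03, and the 11804 probes called between LPS 33 °C and these replicates do not settle it, since a batch could also separate cultures of one condition.

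The LPS-induced set rose less at 33 °C, with a median interaction of -0.324. Compression of dim vehicle values is argued against, since among the 1433 induced probes with vehicle means above the array median it was -0.329. The batch above cannot be told apart from temperature as its cause: with a term for it the median was -0.232 (adjusted p = 0.000846 in limma's fry), but the 37 °C LPS effect then rests on replicate 1 alone, with its spread taken from the other arrays, so the bound set beforehand does not decide. The set was also chosen again with that term, and the less precise 37 °C effect can push its median down. With blocks of 4 arrays in deposition order the median was -0.174 (adjusted p = 0.0111 in limma's fry), so its size stays open too. An effect of temperature on the induction stays among the open explanations.

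The MMU_CIRCpedia probes had a higher median at 33 °C with LPS, past the threshold only at the preset correlation. Dependence on probe brightness is argued against, since the shift was 0.142 after subtracting the shift of cluster probes of like brightness, and 0.112 to 0.178 with any LPS array left out. A batch among the arrays stays open, as does chance, because the test with an estimated correlation did not pass and LPS 37 °C replicate 2, at 1.39, lay nearer the 33 °C arrays than replicates 1 and 3, at 1.26 and 1.24. No biological explanation was tested beyond temperature itself.

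For the 4 contrasts of 3 against 3 arrays, 10 splits are too few for a share under 0.05, and 1 of 10, the real one, gave as many calls. The real and the highest other counts were 17366 and 24 for LPS at 37 °C, 10477 and 1 for LPS at 33 °C, 13723 and 0 for 33 °C without LPS, and 11674 and 2 for 33 °C with LPS. Every other split mixes arrays of both groups, so a difference between the groups enters its residuals and lowers its calls. The low counts of the other splits therefore do not exclude chance.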

How the results depend on the processing

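The settings for the array structure, and the results on temperature shifts, shared counts and LPS-repressed probes, were chosen after seeing the data. Quantile normalization and scaling to the 75th percentile say nothing about stability, since the deposited arrays already share 1 distribution. Averaging of probes per gene and the gene list tests were not run. The LPS-induced median stayed below 0 and past the fry threshold in every setting that recomputed it, between -0.45 and -0.17. Of 405 values of the 20 named probe and contrast pairs under the other settings, 360 kept their call, 45 lost it and 0 reversed. Unless stated, the cause of a change was not tested.

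Counts below are of probes, in the order LPS at 37 °C, LPS at 33 °C, 33 °C without LPS, 33 °C with LPS and interaction. With no filter on dim probes the last 3 were 6551, 7207 and 503, the shared temperature count was 2205 and the correlation of the LPS responses 0.24. A stricter filter gave 3297 for the interaction and a correlation of 0.74. A trended, robust variance gave 3247 for the interaction. Array weights gave 28643, 32501, 35163, 19519 and 20335, with shared counts of 12258 for LPS and 7899 for temperature. The weights were 5.80 for LPS 33 °C replicate 3 and 3.82 for vehicle 33 °C replicate 3, so the weighted 33 °C means rest mainly on that replicate. Fitting only the groups compared gave 11537 for LPS at 37 °C and 3006 for 33 °C with LPS. A 2-fold minimum gave 4275, 2844, 3172, 1858 and 718, by construction.

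The term for the arrays that LPS 37 °C replicate 1 resembles, which leaves the 37 °C LPS effect to replicate 1 alone, gave 10902 for LPS at 37 °C, 558 for 33 °C without LPS, 624 for the interaction and 415 shared for temperature, with a repressed median of 0.38 (adjusted p = 0.000846 in limma's fry). Replicate 1 as the only LPS 37 °C array, assumed to vary like the other groups, gave 10104, 22186, 390 and 8660 for these, with a repressed median of 0.37. Blocks of 4 arrays in deposition order, which are hypothetical, gave 9288, 4939, 172, 746 and 53, with 3446 shared for LPS, 95 for temperature and a repressed median of 0.37. Blocks and groups overlap heavily there, which costs precision, so the loss of calls does not show that the effects are absent.

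Leaving out each array gave 11857 to 27228, 6928 to 13560, 5104 to 22835, 6847 to 11804 and 498 to 12863. The shared counts ranged from 4940 to 7399 for LPS and from 2318 to 4433 for temperature, and the repressed median from 0.0125 to 0.23. The correlation ranged from 0.39 to 0.56 for the LPS responses and from 0.07 to 0.46 for the temperature shifts, and the induced median from -0.45 to -0.27. Same-numbered arrays of different groups did not deviate together (residual correlations -0.18 to 0.11), so the numbers do not pair samples; with the replicate block the counts were 15518, 8929, 11323, 9107 and 809.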

Other observations

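The test of the temperature probes in the LPS arrays was chosen after the values had been seen. The 320 probes that differed at least 4-fold between temperatures without LPS kept their direction with LPS in 86.9% of cases. The share was 80.8% among all 13723 called probes, and both shares include LPS 37 °C replicate 1. The median of the 320 probes was 1.36 with LPS against 2.30 without LPS on the log2 scale. The 2852 probes of 2- to 4-fold had a median of 0.39 with LPS against 1.24 without. The probes were chosen for their size without LPS, so a smaller median with LPS is expected from the choice alone and does not show an effect of LPS. Measured against LPS 37 °C replicates 2 and 3 alone, those medians with LPS were 1.11 and 0.13.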
